A study of Homo sapiens with 40 samples.

How the data were processed

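RNA was measured by sequencing in 40 libraries, 4 replicate cultures of each of 10 lines of the human lung carcinoma line H1299. Per the labels' protocols, total RNA was purified on silica columns, its amount and quality were assessed, and libraries were sequenced on an Illumina NovaSeq X-Plus. The labels name a DNA library kit for this step and record neither enrichment for polyadenylated RNA nor removal of ribosomal RNA. Per the submitters' processing notes, the tools were FastQC 0.12.0, MultiQC 1.24.1, fastp 0.23.4, STAR 2.7.11b and HTSeq 2.0.5, with the human build hg38. The sources used here give neither the strand setting of the counting nor the annotation release.

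The deposited file holds raw counts, whole numbers of reads per gene symbol with no normalization, per the file headers and the values themselves. It lists 59251 gene symbols in 40 columns, and 17548 of the symbols had no count in any library. All columns were matched to samples through the library names that the labels give. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Reads of ribosomal protein, histone, HLA, keratin, cancer-testis and interferon-induced genes can be shared with near-identical copies or pseudogenes, so their counts are uncertain.

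Library totals ran from 40038800 to 44013400 counts (to 6 digits). The cultures of a line correlated with a Spearman coefficient of at least 0.990. Their counts nevertheless varied by 2.45 to 33.6 times what counting error alone gives, measured as a chi-square per degree of freedom over genes with a summed count of at least 40. Intervals and floors from counts given below cover counting error only, since the reads carry no molecular identifiers. In each of the 40 libraries LDHA had between 0 and 3 counts and ZYX between 0 and 10, although both are abundant in most cultured cells. A level near 0 therefore cannot be read as absence of a transcript.

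Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with edgeR's filterByExpr by line (minimum count 10), which left 19703 genes holding 99.96% of all counts. Counts were scaled by trimmed mean of M values (TMM), with factors between 0.952 and 1.06. A negative binomial model with a coefficient per line was fitted to all 40 libraries by edgeR's robust quasi-likelihood method, with 30 residual degrees of freedom and a common biological coefficient of variation of 8.62%. No replicate block was used. Levels are given as CPM, counts relative to the TMM-scaled library total as edgeR's cpm function gives them, and log2 CPM used a prior count of 2.

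Each of 9 comparisons set lines against lines. For comparisons of several clones, a gene's p-value was the largest over every pair of lines across the comparison, or 1 where pairs differed in direction, because the clone is the unit that carries a genotype. P-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05 together with an absolute log2 fold change of at least 1, averaged over lines. Every adjusted p of a gene is from this edgeR quasi-likelihood test, and its log2 fold change is given with its standard error. That standard error is of the average over lines and covers the spread between cultures of a line. It leaves out the spread between clones of a genotype, so it understates the uncertainty of a change over several clones. The fold change of several clones averages their log2 values and departs from the ratio of mean CPM where clones differ. As a separate test with the clone as the unit, counts were summed over the cultures of each line, which left 3 residual degrees of freedom.

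Lists of genes, 29 of pathways and complexes and 5 of markers of other cell types, were fixed before the data were examined, as were the tests, the comparisons and the rule for named genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over all 261 tests of a list in a comparison, and again with an estimated correlation, and for the knockouts on counts summed per clone (adjusted over 58 tests). The adjusted p of a list is from camera on the average over lines, and it rests on the spread between cultures of a line. It does not require pairs of clones to agree and leaves out the spread between clones of a genotype, except on counts summed per clone. Of the 261 tests, 64 passed at the preset correlation and 7 with an estimated one, and the text describes lists chosen among them and among those bearing on MYO10 and JAG1. Genes named are of 4 kinds. The targets MYO10 and JAG1 are given in every line. For JAG1 knockout, MYO10 knockout and leaders against followers, the 12 called genes with the highest and the 12 with the lowest change qualified, ranked by the smallest absolute change over line pairs, among genes of at least 5 CPM in the higher group and with a name other than that of a clone-based, non-coding, antisense or pseudogene entry; for the other comparisons 5 and 5 qualified. Up to 4 called members of each list with the largest change were named, or the 2 with the smallest p where a significant list had none. The last kind is the 10 genes called in both knockouts with the largest smaller change. Some of these were left out for brevity.

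Gene positions came from NCBI RefSeq's gene table on GRCh38, the build that hg38 denotes, matched by symbol. The 10302 genes with a position and a mean of at least 5 CPM were used for chromosome regions. The design had named chromosome arms or the sides of the edited gene. Arms were not used, as the table gives no centromeres, and segments of 20 Mb with at least 20 genes were used besides. That segment size, the simulations with a spread between clones (equal in all, or own to each genotype), the correlations of clones with controls split, the shares of parental levels and the tests of X-linked genes were chosen after the data were seen.

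The model was tested on counts simulated for the 19703 genes tested, to which filterByExpr was applied again. For JAG1 knockout against wild-type clones 18866 genes were kept. Of the genes changed 2-fold 41.8% were called, 100% of those changed 3-fold and 100% of those changed 4-fold, with 0 false calls by edgeR. With counts summed per clone the shares were 44.8%, 98.5% and 100%. For leaders against followers, with 18892 genes kept, they were 50.7%, 98.5% and 100%, with 2 false calls. These simulations held no spread between clones of a genotype.

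Alternatives were DESeq2's Wald test, DESeq2-type size factors, library totals alone, no low-count filter, a filter at 1 CPM, fits to the compared libraries alone, a replicate block, each clone or control alone, limma-voom with the clone as a random block, and leaving out each library in turn. Nothing was left out of the 40 libraries.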

Results

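Gene expression was profiled in 10 lines of H1299, a human non-small cell lung carcinoma line, with 4 biological replicate cultures per line. The lines comprised parental H1299 cells, a leader line and a follower line, names used for cells at the front of collectively invading groups and for those behind them. The other lines were clones that had been through CRISPR-Cas9 editing, in leader cells according to the title of the series. They were 2 clones that stayed wild-type for MYO10 and JAG1 (clones 38 and 75), 2 JAG1 knockout clones (35 and 72), 2 MYO10 knockout clones (98 and 99), and clone 84. The genotype label of clone 84 calls it a MYO10 knockdown while its title calls it a knockout, and it was kept apart as the knockdown clone. Totals per library ran from 40038800 to 44013400 counts (to 6 digits). MYO10 encodes myosin-X, a motor protein found at the tips of filopodia, and JAG1 encodes Jagged-1, a ligand of Notch receptors.

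MYO10, on chromosome 5 from 16661907 to 16936288 (GRCh38), was abundant in leaders and almost undetected in followers. It stood at 645 ± 75.2 CPM (mean ± SD, n = 4) in leaders, 312 ± 81.6 in parentals and 0.112 ± 0.144 in followers, whose libraries held 1 to 13 counts. Wild-type clones 38 and 75 had 491 ± 79.9 and 441 ± 66.9 CPM. MYO10 knockout clones 98 and 99 had 63.4 ± 5.82 and 52.0 ± 5.08, and knockdown clone 84 had 150 ± 27.3, all below both wild-type clones. MYO10 fell by 3.02 ± 0.11 on the log2 scale in the knockout clones (edgeR quasi-likelihood adjusted p = 1.0e-15) and by 1.63 ± 0.13 in the knockdown clone (adjusted p = 4.0e-10). JAG1 knockout clones 35 and 72 had 248 ± 3.96 and 518 ± 16.98 CPM of MYO10.

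JAG1, on chromosome 20 from 10637684 to 10673999, was higher in parentals than in any other line, at 295 ± 53.6 CPM. Leaders had 139 ± 18.7 and followers 17.5 ± 2.62, against 44.2 ± 9.63 and 40.5 ± 1.38 in wild-type clones 38 and 75. The JAG1 knockout clones differed from each other, with 32.4 ± 1.76 CPM in clone 35 and 6.49 ± 0.296 in clone 72, a log2 difference of 2.32 ± 0.20 (adjusted p = 5.1e-12, edgeR). JAG1 was not called over all 4 pairs of knockout and wild-type clones (log2 -1.55 ± 0.13, adjusted p = 0.54), which ran from log2 -2.77 to -0.32. With no low-count filter it was called (adjusted p = 6.4e-05), and over 23 alternatives its adjusted p ran from 6.4e-05 to 0.9997; what moved it was not tested. JAG1 rose in the MYO10 knockout clones (log2 1.10 ± 0.12, adjusted p = 0.00013), at 80.5 ± 13.7 CPM in clone 98 and 102 ± 22.1 in clone 99. It rose in the knockdown clone too (log2 1.83 ± 0.14, adjusted p = 6.2e-10), to 151 ± 41.0 CPM. The labels do not say where the guides cut, so the transcript that remained shows neither presence nor loss of protein.

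**Figure D1:**
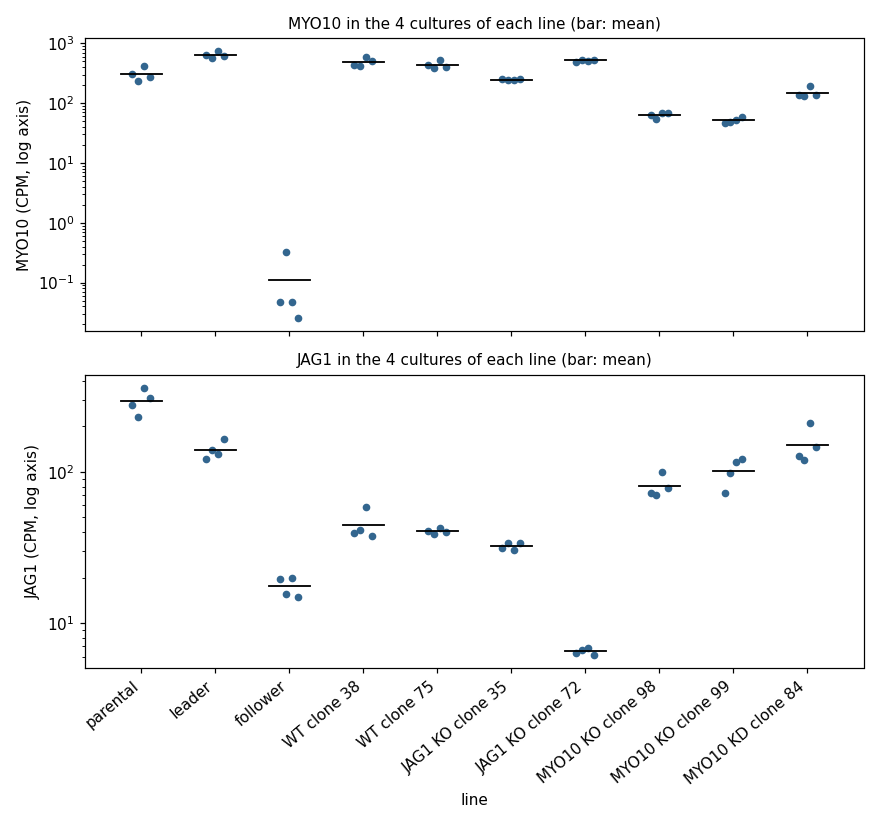
Level of MYO10 (top) and JAG1 (bottom) in CPM on a log axis, with a point per culture and a bar at the mean of the 4 cultures of each of the 10 lines. MYO10 lay at 0.112 CPM in followers and at 63.4 and 52.0 CPM in knockout clones 98 and 99, while JAG1 lay at 6.49 CPM in knockout clone 72 and at 32.4 CPM in knockout clone 35.

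The cultures grouped by line on the first principal components of log2 CPM, which held 24.2% and 22.03% of the variance. Followers stood apart on the first component. On the second, JAG1 knockout clone 35 lay with MYO10 knockout clones 98 and 99, and JAG1 knockout clone 72 lay at the other end, beyond the wild-type clones. The number of genes called between JAG1 knockout clones 35 and 72 was 4138, against 2200 between clones 35 and 98 and 2222 between clones 35 and 99. MYO10 knockout clones 98 and 99 differed in 1882 genes.

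**Figure D2:**
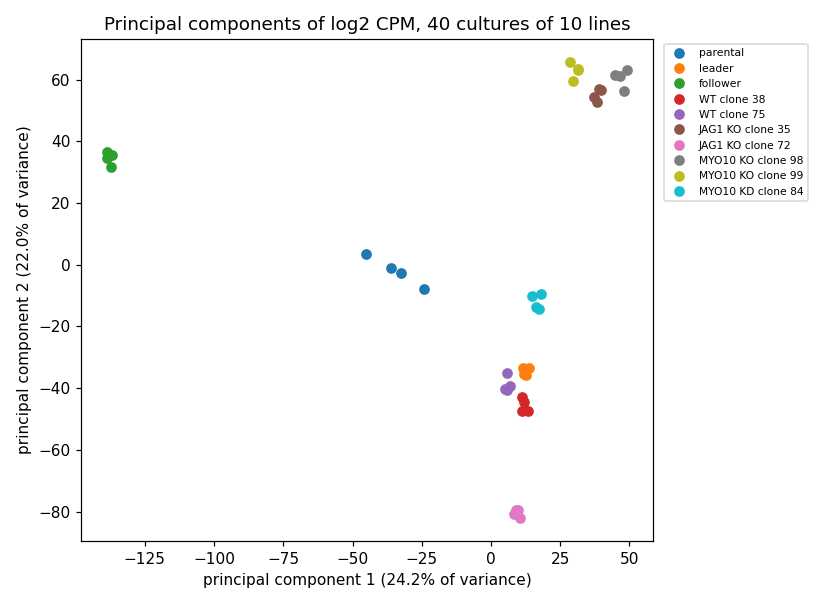
First 2 principal components of log2 CPM, in arbitrary units, with a point per culture and a colour per line. JAG1 knockout clone 35 lies beside MYO10 knockout clones 98 and 99 at the top, JAG1 knockout clone 72 at the bottom, and followers at the left.

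Leaders and followers were compared to ask which genes set leader cells apart. Leaders expressed growth factor IGF2 at 55.3 CPM and collagen VI chain COL6A3 at 32.4 CPM, both without a count in followers (at least 3011-fold and 1767-fold higher, with a floor of 3 counts over the group, n = 4 per line). Collagen V chain COL5A1 and retinaldehyde dehydrogenase ALDH1A3 were likewise at least 963-fold and 633-fold higher. Followers expressed the interleukin receptor IL13RA2 at 72.2 CPM, the mitochondrial transhydrogenase NNT at 37.9 CPM and the pluripotency factor SOX2 at 11.98 CPM, all without a count in leaders (at least 3897-fold, 2049-fold and 647-fold lower in leaders). PMEPA1, a target of TGF-beta, rose from 7.33 CPM in followers to 275 CPM in leaders (log2 5.23 ± 0.24).

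By list, 11 of 19 Notch target genes rose in leaders against followers, 1 fell and 7 did not pass (camera adjusted p = 0.0011, and adjusted p = 0.26 with an estimated correlation). TBX3 rose from 1.63 to 23.0 CPM (log2 3.82 ± 0.14), while HEYL fell (log2 -2.78 ± 0.17). WNT pathway genes and targets rose in 14 of 29 and fell in 2 (adjusted p = 0.0015, and adjusted p = 0.043 with an estimated correlation), among them the ligand WNT9A, from 0.329 to 53.4 CPM (log2 7.34 ± 0.36). Of 22 YAP and TAZ targets 9 fell and 0 rose (adjusted p = 0.0094, and adjusted p = 0.86 with an estimated correlation). They included the receptor kinase AXL, at 281 CPM in leaders and 2186 in followers (log2 -2.96 ± 0.15), and ANKRD1 (log2 -3.87 ± 0.47). Cancer-testis genes fell in 7 of 11 (adjusted p = 0.0036, and adjusted p = 0.30 with an estimated correlation), with MAGEA10 at 0.309 against 57.3 CPM (log2 -7.52 ± 0.18). Ribosomal protein genes fell in 3 of 68 (adjusted p = 0.0022, and adjusted p = 0.96 with an estimated correlation): RPS16, RPS19 and RPL10, by log2 -1.85 ± 0.05, -1.67 ± 0.05 and -1.54 ± 0.05. RPS16 lies in a segment of chromosome 19 whose 126 genes had a median of log2 1.15 in followers and -0.51 in leaders, set against the median of the 10 lines. RPL10 and MAGEA10 lie in a segment of chromosome X whose 53 genes had a median of 1.38 in followers. Of 36 genes of filopodia and actin bundling 1 rose and 4 fell (adjusted p = 0.64), with EPS8 at log2 1.49 ± 0.09 and VASP at -1.54 ± 0.06; the list's mean was -0.16 where its median was 0.05 and its test pointed up. The same counts passed in these lists when adjusted over the list alone. In all, 2505 genes rose and 2508 fell. The groups are a line each, so the test measures the spread between cultures and not between leader or follower lines.

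Leaders against parentals asked what marks the leader line within its population of origin. Genes of the interferon response rose in 18 of 39 and fell in 1 (adjusted p = 3.4e-11, and adjusted p = 0.061 with an estimated correlation), led by OASL, at 12.9 against 0.0763 CPM (log2 7.35 ± 0.34). Antigen presentation genes rose in 4 of 14 and fell in 0 (adjusted p = 0.00046, and adjusted p = 0.082 with an estimated correlation). Among them were the class II chain HLA-DRB1 (log2 7.23 ± 0.37), the invariant chain CD74, from 0.147 to 10.2 CPM (log2 6.10 ± 0.27), and the class II activator CIITA, from 5.15 to 13.9 CPM. Neuronal and axon guidance genes fell in 11 of 33 and rose in 2 (adjusted p = 0.0022, and adjusted p = 0.60 with an estimated correlation), with contactin CNTN1 at 0.0677 against 5.32 CPM (log2 -6.23 ± 0.30). IL13RA2 had 12.8 CPM in parentals and was at least 693-fold lower in leaders, which had no count. Cancer-testis genes fell in 2 of 11, including MAGEA10 (log2 -5.12 ± 0.20; list adjusted p = 0.0018, and adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, these counts were the same.

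MYO10 rose in leaders against parentals (log2 1.05 ± 0.14) and JAG1 fell (log2 -1.08 ± 0.16), both near the threshold of 1. MYO10 dropped under it with library totals alone (0.99), without leader replicate 3 (0.98) and without parental replicate 2 (0.94), and JAG1 without parental replicate 3 (-0.96). In all, 635 genes rose and 1288 fell.

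In followers against parentals, Notch target genes fell in 10 of 19 and rose in 0 (adjusted p = 3.0e-05, and adjusted p = 0.082 with an estimated correlation). HES4 fell from 47.7 to 7.92 CPM (log2 -2.59 ± 0.23) and HEY2 by log2 -2.43 ± 0.16. Receptor NOTCH1 (log2 -2.18 ± 0.08) and ligand JAG2 (log2 -2.57 ± 0.13) fell besides, in a list of Notch receptors, ligands and modulators of which 4 of 31 rose and 6 fell (adjusted p = 0.78; median 0.10, mean -0.12, test pointing up). WNT pathway genes fell in 12 of 29 and rose in 2 (adjusted p = 0.0053, and adjusted p = 0.072 with an estimated correlation), with WNT9A at 0.329 against 49.04 CPM. YAP and TAZ targets rose in 7 of 22 and fell in 1 (adjusted p = 0.0017, and adjusted p = 0.83 with an estimated correlation), including AXL (log2 2.50 ± 0.14) and IGFBP3, from 3.12 to 56.5 CPM (log2 4.17 ± 0.24). Interferon response genes rose in 17 of 39 and fell in 3 (adjusted p = 0.0001, and adjusted p = 0.47 with an estimated correlation), with IFI44 from 0.222 to 3.73 CPM. Replication-dependent histone genes rose in 10 of 33 (adjusted p = 0.038, and adjusted p = 0.89 with an estimated correlation), with H2BC9 at log2 1.79 ± 0.16. IGF2 and COL5A1 had no count in followers and were at least 961-fold and 634-fold lower than in parentals, while the lipase MGLL rose (log2 5.06 ± 0.22). Adjusted over the list alone, each of these counts was the same. In all, 1836 genes rose and 2156 fell.

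The wild-type clones served as the background of clone-to-clone difference. Clone 38 differed from clone 75 in 861 genes, 322 higher and 539 lower. The chemokine CCL2 had 2.84 CPM in clone 38 and 50.0 in clone 75 (log2 -4.14 ± 0.25), and the Notch-related membrane protein DNER 26.3 against 0.379 (log2 6.10 ± 0.26). Thrombospondin THBS1 was higher in clone 38, at 58.6 against 12 CPM. Glycolysis and hypoxia genes, of which only NDRG1 of 34 was called (0.862 against 0.0861 CPM, log2 3.27 ± 0.47), leaned higher in clone 38 (adjusted p = 1.0e-05, and adjusted p = 0.062 with an estimated correlation; also 1 when adjusted over the list alone).

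Wild-type clones against the unedited leader line addressed what cloning and editing go with in clones labelled wild-type for both targets. Interferon response genes fell in 17 of 39 and rose in 0 (adjusted p = 1.4e-05, and adjusted p = 0.37 with an estimated correlation), OASL from 12.9 to 0.0270 CPM (log2 -8.98 ± 0.30). WNT pathway genes fell in 7 of 29 and rose in 1 (adjusted p = 0.0012, and adjusted p = 0.043 with an estimated correlation), with receptor ROR2 at 0.0181 against 6.59 CPM. Extracellular matrix genes fell in 16 of 47 and rose in 6 (adjusted p = 0.025, and adjusted p = 0.53 with an estimated correlation), COL6A3 from 32.4 to 0.122 CPM (log2 -8.13 ± 0.34). Matrix proteases and inhibitors fell in 8 of 25 and rose in 1 (adjusted p = 0.0025, and adjusted p = 0.26 with an estimated correlation), with MMP2 at log2 -6.03 ± 0.43. CCL2 rose from 0.272 to 26.4 CPM (log2 5.44 ± 0.33), and HLA-DRB1 had no count in the 8 wild-type libraries, at least 641-fold lower. JAG1 fell by 1.72 ± 0.14 on the log2 scale. Adjusted over the list alone, no count changed. In all, 1011 genes rose and 956 fell.

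JAG1 knockout clones were compared with the wild-type clones by their label, since JAG1 changed by log2 -2.70 in clone 72 but by -0.39 in clone 35, less than the median of its neighbours there. Extracellular matrix genes fell in 11 of 47 and rose in 0 (adjusted p = 2.8e-06, and adjusted p = 0.043 with an estimated correlation). The crosslinking enzyme LOXL1 fell from 8.65 to 1.058 CPM (log2 -5.92 ± 0.27, averaged over clones at 2.11 CPM in clone 35 and 0.006135 in clone 72), COL12A1 from 10.4 to 1.5 CPM (log2 -2.53 ± 0.22) and COL18A1 from 6.08 to 1.10 CPM (log2 -2.46 ± 0.11). The growth factor TGFA fell from 68.1 to 1.39 CPM (log2 -5.52 ± 0.14), monoamine oxidase MAOA from 12.5 to 0.0946 CPM (log2 -7.02 ± 0.16) and the semaphorin SEMA6B from 67.1 to 7.83 CPM (log2 -3.22 ± 0.22). Genes that rose included the bone morphogenetic protein relative GDF6, from 0.961 to 22.1 CPM (log2 4.51 ± 0.16), the receptor TGFBR2, from 12.6 to 77.2 CPM (log2 2.45 ± 0.08), the neuregulin NRG1 (log2 2.77 ± 0.18) and the kinase SGK1, from 67.6 to 213 CPM (log2 1.66 ± 0.15).

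Of 19 Notch target genes 1 rose, GATA3 (log2 2.97 ± 0.12), and 18 did not pass in the JAG1 knockout clones (adjusted p = 0.80). Of 31 Notch receptors, ligands and modulators 1 fell, the ubiquitin ligase partner DTX3L (log2 -1.50 ± 0.06; list adjusted p = 0.64). Epithelial genes fell in 6 of 26 (adjusted p = 0.0083, and adjusted p = 0.16 with an estimated correlation), with the desmosomal cadherin DSG2 at 9.23 against 31.5 CPM (log2 -1.84 ± 0.08). Interferon response genes fell in 4 of 39 (adjusted p = 0.012, and adjusted p = 0.83 with an estimated correlation), with OAS3 at 21.0 against 66.8 CPM (log2 -1.76 ± 0.05). Of 25 NF-kB cytokines and chemokines 3 fell, CCL2, CSF1 and ICAM1, the last from 65.7 to 16.7 CPM (log2 -2.39 ± 0.16; list adjusted p = 0.24). All these counts were the same when adjusted over the list alone.

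In all, 61 genes rose and 345 fell over all 4 pairs of JAG1 knockout and wild-type clones, 406 together. Simulated clones without any genotype effect gave 579 on average (538 to 615) with the spread of each genotype's own clones. With an equal spread they gave 414 (394 to 432). The number of calls is thus no larger than a spread between clones alone gives. Against the same wild-type clones, the log2 fold changes of clones 35 and 72 had a Pearson correlation of 0.0548 across genes, which are not independent replicates, where simulated unchanged clones gave 0.108 on average and 0.0590 to 0.146 over 12 simulations that gave each genotype the spread of its own 2 clones. The covariance was 0.0623, and 0.112 on average (0.0615 to 0.151) in the simulations. With an equal spread for wild-type and edited clones, which alone brings the correlation near 0.330, the simulated covariance was 0.257. With a different wild-type clone for each, which removes the shared controls, the correlation was -0.0755 and -0.00636. With the clone as the unit and counts summed per clone, edgeR called 0 genes (1135 at an unadjusted p under 0.05) and DESeq2 182.

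MYO10 knockout clones were compared with the same wild-type clones. The secreted phosphoprotein SPP1 rose from 0.0291 to 176 CPM (log2 12.65 ± 0.34), the LIM protein CRIP1 from 1.36 to 179 CPM (log2 7.07 ± 0.14) and keratin KRT8 from 22.7 to 453 CPM (log2 4.32 ± 0.10). Receptor NOTCH3 rose from 2.19 to 24.4 CPM (log2 3.47 ± 0.21), GATA3 from 2.18 to 27.5 CPM (log2 3.66 ± 0.12) and the protease inhibitor SERPINE2 from 1.82 to 26.7 CPM (log2 3.84 ± 0.23). The mesenchymal cadherin CDH2 fell from 40.02 to 6.20 CPM (log2 -4.93 ± 0.09, averaged over clones at 0.137 CPM in clone 98 and 12.3 in clone 99), the kinase subunit PRKAA2 from 30.8 to 0.216 CPM (log2 -7.20 ± 0.09), and SLFN11, a factor in the response to DNA damage, had no count in the 8 knockout libraries (at least 747-fold lower). SLFN11 was also near 0 in the unedited leader line, at 0.0240 CPM against 6.44 in the wild-type clones. In this gene the wild-type clones were the ones that differed from leaders. In all, 968 genes rose and 620 fell.

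Cholesterol synthesis genes fell in 6 of 28 and rose in 0 in the MYO10 knockout clones (adjusted p = 7.5e-05, and adjusted p = 0.87 with an estimated correlation), with INSIG1 from 103 to 25.1 CPM (log2 -2.04 ± 0.20) and HMGCS1 from 152 to 54.3 CPM (log2 -1.49 ± 0.13). Antigen presentation genes fell in 3 of 14 (adjusted p = 0.019, and adjusted p = 0.46 with an estimated correlation), HLA-B by log2 -1.49 ± 0.04 (-2.42 to -0.57 over pairs of clones) and HLA-C by -1.51 ± 0.05 (-2.51 to -0.51). VEGF and angiogenesis genes rose in 6 of 33, or 7 when adjusted over the list alone, and fell in 1 (adjusted p = 0.031, and adjusted p = 0.55 with an estimated correlation), with the hypoxia factor EPAS1 reaching 21.1 CPM (log2 4.40 ± 0.24). With counts summed per clone, neither the antigen presentation list nor the VEGF list passed (camera adjusted p = 0.10 for each). G2 and M phase genes passed as a list with a median of log2 -0.44 and 0 of 37 called (adjusted p = 1.1e-07, and adjusted p = 0.85 with an estimated correlation). S phase genes passed with PCNA alone of 32 called, from 240 to 103 CPM (log2 -1.23 ± 0.06; list adjusted p = 1.8e-06, and adjusted p = 0.83 with an estimated correlation). Epithelial genes went both ways, 9 of 26 up and 6 down (adjusted p = 0.20). The list tests kept the genes of chromosome segments that changed as a block. An example is the start of chromosome 20, with medians of log2 -0.64 in clone 98 and -0.42 in clone 99, set against the median of the 10 lines. Regional changes and changes of a pathway were thus not separated in these lists or their members.

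Of the 36 genes of filopodia and actin bundling 4 rose in the MYO10 knockout clones and 0 fell (adjusted p = 0.82, with a median of log2 -0.17, a mean of 0.15 and a test pointing down). They included fascin FSCN1, from 133 to 278 CPM (log2 1.08 ± 0.06), and BAIAP2 (log2 1.19 ± 0.05). Of 19 other unconventional and non-muscle myosins MYO5C rose (log2 2.68 ± 0.12) and MYO6 fell (log2 -1.62 ± 0.06; list adjusted p = 0.99). Notch target genes rose in 5 of 19 and fell in 0 (adjusted p = 0.45), HES7 by log2 1.71 ± 0.10 and NRARP by 1.59 ± 0.07. Apart from the VEGF list, the counts of the MYO10 knockout lists were the same when adjusted over the list alone. With counts summed per clone, edgeR called 0 genes (2376 at an unadjusted p under 0.05), edgeR on the 4 clones alone 283 and DESeq2 545.

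In knockdown clone 84, interferon response genes rose in 21 of 39 and fell in 0 against the wild-type clones (adjusted p = 3.6e-12, and adjusted p = 0.043 with an estimated correlation), with OASL from 0.0270 to 24.6 CPM (log2 9.91 ± 0.29) and IFI44 from 0.0949 to 16.6 CPM (log2 7.93 ± 0.25). WNT pathway genes rose in 9 of 29 and fell in 0 (adjusted p = 4.6e-05, and adjusted p = 0.018 with an estimated correlation), with ROR2 from 0.0181 to 1.27 CPM. TGF-beta pathway genes rose in 6 of 29, or 7 when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.50 with an estimated correlation), with TGFBR2 from 12.6 to 48.2 CPM (log2 1.98 ± 0.09). Extracellular matrix genes rose in 13 of 47 and fell in 3 (adjusted p = 0.026, and adjusted p = 0.53 with an estimated correlation), THBS1 from 35.3 to 307 CPM (log2 3.53 ± 0.28) and fibronectin FN1 from 61.5 to 318 CPM (log2 2.53 ± 0.22). The desmosomal protein DSP rose to 135 from 7.79 CPM (log2 4.71 ± 0.13), and NUDT12 had no count in the clone, at least 376-fold lower.

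Mitochondrially encoded genes took 5.09 ± 0.338% (SD) of counts in clone 84, 2.98 ± 0.497% in clone 38 and 3.83 ± 0.519% in clone 75, and 0 of their 13 genes were called by edgeR (list adjusted p = 0.00017, and adjusted p = 0.83 with an estimated correlation). In all, 1047 genes rose and 369 fell in the knockdown clone. It is a single clone, so clone and genotype cannot be separated in this comparison. Several interferon response and WNT pathway genes that rose, such as OASL and ROR2, were also lower in the wild-type clones than in leaders.

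JAG1 knockout clones were set directly against MYO10 knockout clones. List tests on counts summed per clone were not run for this comparison, so its list p-values leave out the spread between clones. Extracellular matrix genes were lower in the JAG1 knockout clones in 15 of 47, or 17 when adjusted over the list alone, and higher in 0 (adjusted p = 2.4e-07, and adjusted p = 0.040 with an estimated correlation), with FN1 at 32.3 against 182 CPM (log2 -2.70 ± 0.20). Epithelial genes were lower in 7 of 26, or 8 over the list alone (adjusted p = 0.00049, and adjusted p = 0.043 with an estimated correlation), with plakoglobin JUP at 0.873 against 6.18 CPM (log2 -3.50 ± 0.18, and -5.68 to -1.31 over pairs of clones). Integrin and focal adhesion genes were lower in 4 of 28 (adjusted p = 0.00058, and adjusted p = 0.26 with an estimated correlation), ITGA3 at 57.2 against 200 CPM (log2 -1.85 ± 0.10). CDH2 was higher, at 69.4 against 6.20 CPM (log2 5.19 ± 0.09, and 0.64 to 9.74 over pairs of clones), as was the transporter SLC7A2 (log2 3.08 ± 0.07). The targets differed in the directions of the labels, MYO10 by log2 2.64 ± 0.11 and JAG1 by log2 -2.64 ± 0.13. Part of the JAG1 difference was its higher level in the MYO10 knockout clones than in the wild-type clones, which lay below unedited leaders. Against the wild-type clones, JAG1 was not called in the JAG1 knockout clones. In all, 140 genes were higher and 532 lower in the JAG1 knockout clones.

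Both knockouts, set against the same wild-type clones, shared 135 called genes in the same direction, 31 higher and 104 lower, with 4 in opposite directions. CCL2 fell in both (log2 -7.14 ± 0.30 in JAG1 knockout, -10.15 ± 0.40 in MYO10 knockout), as did FAM133A (-7.79 ± 0.21 and -6.73 ± 0.19) and MAOA (-7.02 ± 0.16 and -4.42 ± 0.12). CCL2 differed between the wild-type clones too, at 2.84 CPM in clone 38 and 50.0 in clone 75. It was also lower in unedited leaders than in the wild-type clones, so its fall may lie in part with the shared controls. GDF6 rose in both (4.51 ± 0.16 and 4.28 ± 0.16), as did CRACR2A (4.89 ± 0.21 and 6.14 ± 0.19) and MGST1, which itself differed between the wild-type clones, at 6.88 CPM in clone 38 and 0.0169 in clone 75. Independent lists of these sizes would share 3.00 higher and 10.9 lower genes.

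Simulated clones without any genotype effect, sharing the wild-type clones, shared a number of genes that depended on the spread given to the clones. With the spread of its own 2 clones for each genotype, they shared 45.9 genes on average over 12 simulations and 54 at most, with 579 and 245.5 genes called for JAG1 and MYO10 knockout on average. These simulations had 1052 genes called between the wild-type clones, 3291 between clones 35 and 72 and 1734 between clones 98 and 99, on average, where 861, 4138 and 1882 were observed. With an equal spread for all clones, 104 genes were shared on average and 126 at most over 12 simulations, and 106.5 and 124 over 12 others, which put 2596 genes between the wild-type clones. With noise between cultures alone, 4 simulations gave 0 called genes by the same edgeR test. The covariance of the fold changes was 0.450 as observed, and on average 0.110 with own spread, 0.257 with equal spread and 0.0202 with culture noise alone. The Pearson correlation was 0.537 as observed, and on average 0.264, 0.4996 and 0.503. By clone, the observed covariance with clones 98 and 99 was 0.966 and 0.929 for clone 35. For clone 72 it was -0.0218 and -0.0736, where simulations with own spread gave 0.111 and 0.113 on average. The covariance above the simulated one thus came from clone 35 and was not shared by both JAG1 knockout clones. With the wild-type clones split between the knockouts, 229 and 196 genes were shared and 44 and 50 went in opposite directions, in longer lists of 856 and 745 genes for JAG1 knockout and 2062 and 2346 for MYO10 knockout, with covariances of 0.354 and 0.316.

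Genes that set leaders apart from followers were followed in the edited clones as the median log2 fold change of the 2505 leader-high genes minus that of the 2508 follower-high genes. The difference was -0.09 in JAG1 knockout, -0.24 in MYO10 knockout and 0.11 in the knockdown clone. Other choices moved it: in JAG1 knockout to -0.011 against clone 75 alone and -0.15 against clone 38 alone or with genes at 4-fold, and in the knockdown clone to 0.44 with genes at 4-fold and 0.17 against clone 75 alone. Clone by clone it was -0.23 in clone 35, 0.04 in clone 72, -0.13 in clone 98 and -0.30 in clone 99. Wild-type clone 38 against clone 75 gave 0.08, and splits that mixed wild-type and knockout clones gave between -0.07 and 0.16. By camera, leader-high genes leaned lower in JAG1 knockout (p = 0.020, and p = 0.062 with an estimated correlation), follower-high genes higher in MYO10 knockout (p = 0.031, and p = 0.31 with an estimated correlation), and leader-high genes higher in the knockdown clone (p = 0.00022, and p = 0.0043 with an estimated correlation). Follower-high genes had camera p-values as small in some contrasts where genotypes did not differ, 0.030 for wild-type clone 38 against 75, and 0.0011 and 0.00091 in splits that mixed wild-type clones with JAG1 or MYO10 knockout clones, values no larger than the 0.031. With an estimated correlation these were 0.31, 0.13 and 0.12. The remaining mixed splits, with JAG1 and with MYO10 knockout clones, gave camera p = 0.092 and 0.38 (0.43 and 0.68 with an estimated correlation). By JAG1 knockout clone, leader-high genes had a median of log2 -0.15 in each. Their camera p was 0.0041 in clone 72 (0.023 with an estimated correlation) and 0.42 in clone 35 (0.50). In clone 72 follower-high genes leaned lower as well (median -0.19, camera p = 0.0032, and p = 0.17 with an estimated correlation). Called genes of each edited group were more often leader-high and more often follower-high than independent lists give. Of the genes that rose, 406 were leader-high (133 for independent lists) and 254 follower-high (133) in the knockdown clone, 218 (123) and 298 (123) in MYO10 knockout, and 17 (7.76) and 17 (7.76) in JAG1 knockout. Of those that fell, 66 (46.9) and 117 (47.0) were leader-high and follower-high in the knockdown clone, 162 (78.8) and 175 (78.9) in MYO10 knockout, and 92 (43.9) and 114 (43.9) in JAG1 knockout.

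The genes around each target were compared with the wild-type clones as well. Over the 19 other expressed genes within 10 Mb of MYO10, the median log2 fold change was -0.73 in knockout clone 98 (95% bootstrap interval -0.89 to -0.55), -1.62 in knockout clone 99 (-1.74 to -1.44) and -1.40 in knockdown clone 84 (-1.56 to -1.16). MYO10 itself stood at -2.87, -3.16 and -1.63. The 35 genes on the side of MYO10 toward the start of chromosome 5 had medians of -0.69, -1.34 and -1.16, and the 445 genes on its other side 0.06, 0.07 and 0.08. The lower levels nevertheless went on past MYO10 in 2 clones: set against the median of the 10 lines, the 22 genes from 31400500 to 39074400 had a median of -0.79 in clone 99 and -0.70 in clone 84, and the 41 genes from 40679900 to 60522100 one of -0.64 in clone 84 (positions to 6 digits). Over the 74 genes within 10 Mb of JAG1 the median was -0.63 (-0.83 to -0.42) in knockout clone 35, where JAG1 stood at -0.39, and -0.11 (-0.21 to -0.09) in knockout clone 72, where JAG1 stood at -2.70.

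**Figure D3:**
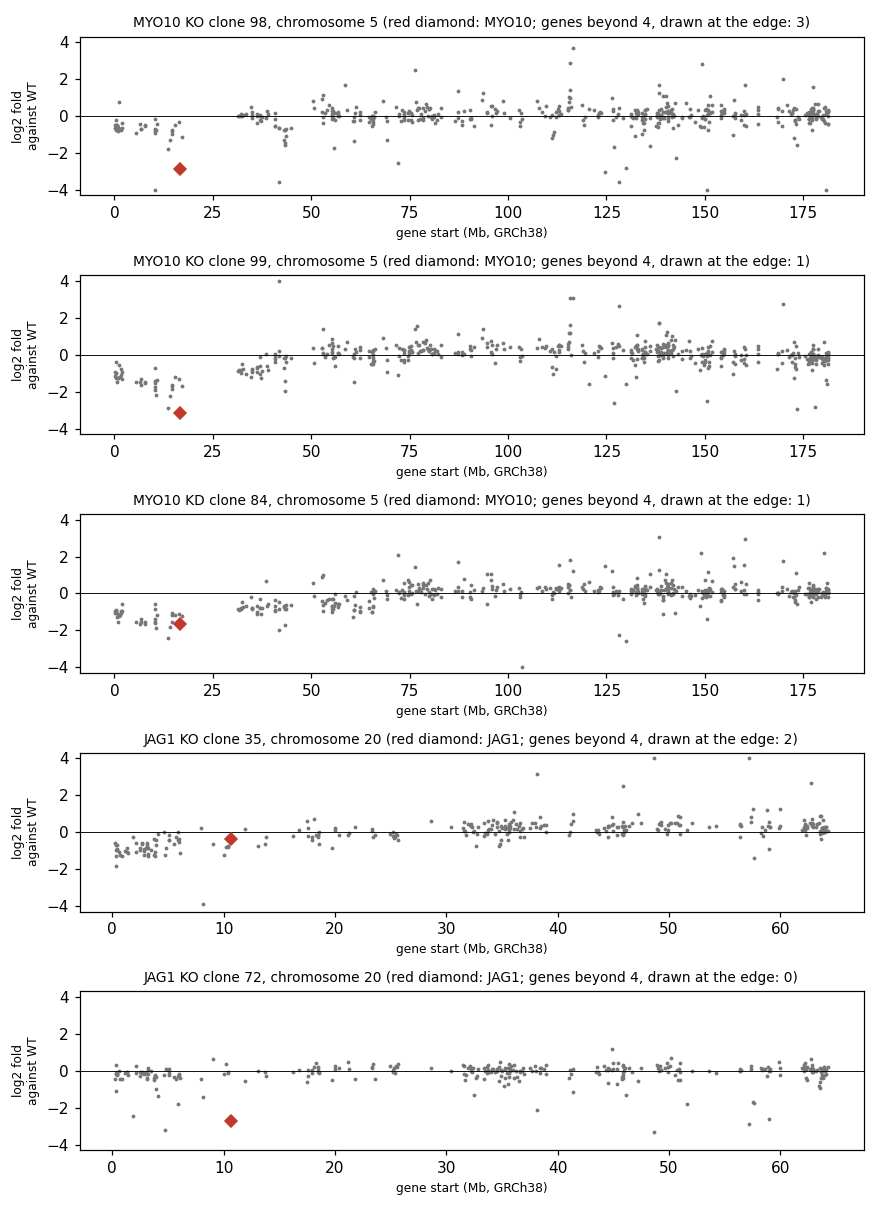
Log2 fold change against the wild-type clones of each expressed gene by its start in Mb on chromosome 5 (clones 98, 99 and 84) or chromosome 20 (clones 35 and 72), with a point per gene and a red diamond for the target; genes beyond 4 are drawn at the edge. Genes between the start of chromosome 5 and MYO10 had medians of -0.69, -1.34 and -1.16 in clones 98, 99 and 84, and all 445 beyond MYO10 medians of 0.06, 0.07 and 0.08, with lower levels just past MYO10 in clones 99 and 84.

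Of markers of other cell types, under 1 CPM in every line were 10 of 14 leukocyte markers, 8 of 8 red blood cell markers, 6 of 8 endothelial markers, 9 of 10 fibroblast markers and 4 of 6 markers of an embryonic kidney line. The highest of each were CD68 (108 CPM in clone 35), SLC4A1 (0.103 in clone 99), EGFL7 (49.3 in clone 98), COL1A1 (7.73 in parentals) and CDH2 (120 in clone 72), of which CD68, EGFL7 and CDH2 are also expressed by carcinoma lines. CD68, EGFL7 and ITGAM were expressed in every line, at 51.7, 15.3 and 3.24 CPM in the lowest.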

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

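Tests chosen only after the result was seen are those of the target's distance from its neighbouring genes (whose measure was also changed after values were seen, from a count of neighbours to a difference), of a mislabelled clone 35 (both), the correlations with simulated clones and with controls split, and both tests of mixed parental cultures. Of 40 groups of 4 cultures (MYO10, JAG1, the library total and the mitochondrial share in each of 10 lines), 3 held a culture far from the others, all of them among the 20 groups of MYO10 and JAG1, and chance gives about 1 in 20. MYO10 stood at 0.327 CPM in follower replicate 2 (nearest other 0.0478) and at 191 CPM in replicate 3 of knockdown clone 84 (nearest other 140). JAG1 stood at 58.5 CPM in replicate 3 of wild-type clone 38 (nearest other 41.1).

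Clones of a genotype differed from each other by edgeR's quasi-likelihood test of that difference: 4138 genes were called between JAG1 knockout clones 35 and 72, and 1882 between MYO10 knockout clones 98 and 99. JAG1 itself differed between clones 35 and 72 by log2 2.32.

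The first pattern is the level of each target in its edited clones, set against loss of the chromosome region around it. Loss of the region as the whole cause is argued against in MYO10 knockout clones 98 and 99 and in JAG1 knockout clone 72, where the target lay below the median of its neighbours by log2 -2.14, -1.54 and -2.60, beyond the neighbours' interquartile range. In knockdown clone 84 and JAG1 knockout clone 35 the distances were -0.24 and 0.24, within that range, and the neighbours' medians were -1.40 and -0.63, so a regional change may account for the target's level there. The neighbours' medians of -0.73 and -1.62 in clones 98 and 99 leave open a regional loss as a part of the change, while that of -0.11 in clone 72 (95% interval -0.21 to -0.09) lies below 0 and does not reach the -0.3 set for a regional loss. In followers against leaders the neighbours' median was -0.18 (-0.46 to -0.12), below 0 with an interval on both sides of -0.3, and MYO10 lay -12.29 from it, which argues against regional loss as the whole cause of its low level.

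The next pattern is that the changes of JAG1 knockout clone 35 from the wild-type clones correlated with those of MYO10 knockout clones 98 and 99 (Pearson 0.686 and 0.683 across genes, which are not independent replicates) and not with those of JAG1 knockout clone 72 (0.0548), where simulated unchanged clones sharing the wild-type clones, each genotype with the spread of its own clones, gave 0.154, 0.146 and 0.108 on average (covariances 0.966, 0.929 and 0.0623 observed, 0.112, 0.106 and 0.112 simulated). With a different wild-type clone for each, the correlations were 0.549 to 0.569 with clone 98 and 0.548 to 0.557 with clone 99. Chromosome segments shared with clones 98 and 99 are argued against as the whole cause, since the lower of the 2 correlations was 0.722 without genes of segments past the threshold, and 0.588 or more with the controls split as well. A mislabelled clone of the kind of 98 and 99 is argued against by MYO10, which in the lowest library of clone 35 stood at 3.58 times their highest library, but at 1.27 times the highest of clone 84 and at log2 -0.91 from the wild-type clones it leaves open a mislabelled clone of the kind of 84. Clones 35 and 84 differed in other measures, which were not part of that test. JAG1 stood at 32.4 CPM in clone 35 and 151 in clone 84, and the neighbours of MYO10 had medians of log2 -0.16 and -1.40. A common origin of clones 35, 98 and 99 from a subset of the edited cells was not tested, nor was a biological explanation.

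The last pattern is that 21 genes listed at 3 counts or fewer in leaders lay in parentals at a median of 17.7% of their follower level (quartiles 15.3% and 22.4%), between 10.3% and 25.4% by library. Parental cultures that hold follower-like cells are a candidate explanation: of 1035 other follower-high genes, 89.9% were higher in the library with the largest share than in that with the smallest, against 13.1% of 716 leader-high genes. A mix of the follower and leader lines alone is argued against, since 14 genes at 3 counts or fewer in followers lay in parentals at an upper quartile of 0.657 of their leader level, where such a mix needs 0.823. Lower expression in all parental cells was not tested against a mixture.

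Other splits of the libraries gave as large a count of called genes in 1 split in each of 9 comparisons, the real one itself. Cultures of a line resemble each other, so a split that mixes lines tends to call fewer genes whatever the genotype. The test therefore cannot exclude chance differences between clones or lines as the source of these counts. The wild-type clones, of the same genotype, passed it as well. Over 50 splits, the real and the highest other counts were 754 and 0 for JAG1 knockout, 1847 and 16 for MYO10 knockout, 1379 and 0 for the knockdown clone, 1311 and 299 for JAG1 against MYO10 knockout, and 1986 and 495 for wild-type clones against leaders. Over 35 splits they were 4173 and 0 for leaders against followers, 1483 and 0 for leaders against parentals, 3245 and 0 for followers against parentals, and 641 and 0 between the wild-type clones. These fits ignore clones. Splits of the clones number 3 and are too few for a share under 0.05, with 1 as large: real and highest other were 406 and 225, 1588 and 57, 1416 and 593, 672 and 336, and 1967 and 461, in the order of the comparisons over 50 splits.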

How the results depend on the processing

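Of 724 pairs of a named gene and a comparison, none changed direction under the alternatives run on them. Those were the changes of scaling, filter and test, the replicate block, the compared libraries alone and leaving out 1 library. Most of these genes were called, which requires pairs of lines to agree in direction, so a reversal was unlikely. Single clones or controls, leaders as the control, limma-voom and summed counts were run for numbers of calls or the leader gene difference only. The calls lost were 7 with DESeq2, 10 with library totals alone, 11 of 677 with the compared libraries alone, 8 with no low-count filter (1 gained), 2 with DESeq2-type size factors, 1 of 558 at a minimum of 1 CPM, and 202 of 8212 values on leaving out 1 library. Where no reason is given below, the cause was not tested.

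By adjusted p alone, with no fold threshold and so more genes by construction, calls numbered 1244 (JAG1 knockout), 4680 (MYO10 knockout), 5664 (knockdown), 1940 (JAG1 against MYO10 knockout), 12818 (leaders against followers), 7305 (leaders against parentals), 12024 (followers against parentals), 5029 (wild-type clones 38 and 75) and 6720 (wild-type clones against leaders). At 1 CPM or more on average, which tests fewer genes, they were 1053 (MYO10 knockout), 760 (knockdown), 2563, 885, 1931, 387 and 1102 (the last 5 in the order above). For JAG1 knockout, 8 against 8 libraries gave 753, clone 35 alone 2610, clone 72 alone 1551, leaders as the control 1879 and the mean contrast alone 1707. For MYO10 knockout, clones 98 and 99 alone gave 2701 and 2418, leaders as the control 3112 and the mean contrast 2815. A single clone or the mean contrast asks less of a gene by construction. On counts summed per clone, where edgeR called 0 and 0 genes (1135 and 2376 at an unadjusted p under 0.05), DESeq2 called 182 and 545, and edgeR on the 4 clones alone 283 for MYO10 knockout. Limma-voom with the clone as a random block called 290 and 1063. With an estimated correlation 7 list tests passed, and 229 genes were shared by the knockouts with controls split. Simulated clones without effect shared 104 genes at equal spread and 45.9 at the spread of each genotype's own clones. Segments past the threshold numbered 158 at 20 Mb and 226 at 10 Mb. The correlation of the changes of clones 35 and 72 (0.0548) turned to -0.0755 and -0.00636 with controls split, which removes the shared controls by construction.

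The median difference of leader genes in JAG1 knockout was -0.15 with a 4-fold set, -0.15 against clone 38 alone and -0.011 against clone 75 alone. In MYO10 knockout it was -0.29 and -0.16 against these clones, and in the knockdown clone 0.44 with the 4-fold set and 0.17 against clone 75.

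Leaving out 1 library gave 367 to 395 calls for JAG1 knockout, 1534 to 1591 for MYO10 knockout, 1348 to 1420 for the knockdown, 583 to 695 for JAG1 against MYO10 knockout, 5003 to 5114 for leaders against followers, 1827 to 2034 for leaders against parentals, 3910 to 4216 for followers against parentals, 800 to 894 between wild-type clones and 1890 to 2018 for wild-type clones against leaders. The leader gene difference ran from -0.11 to -0.07, from -0.27 to -0.21 and from 0.08 to 0.15.

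The labels do not say that a replicate number marks a shared day or batch, and the numbers were not taken as pairs because 74 of 180 same-number pairs of cultures, and not all, correlated over 0.1. Same-number cultures of different lines correlated at 0.081 on average (-0.43 to 0.68) and different-number cultures at -0.026. Genes were centred within each line, which largely fixes the different-number average from the same-number one, so the former adds no evidence. Of 40 libraries 23 correlated best with their own number, a hint from the data that cultures of a number share something. A replicate block gave 412 calls for JAG1 knockout and 1611 for MYO10 knockout, and ended 3 calls of named genes.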

Other observations

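The test of X-linked genes was chosen only after the result was seen. Matrix proteases and inhibitors rose in 7 of 25 and fell in 1 in knockdown clone 84 against the wild-type clones (camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). In the MYO10 knockout clones 5 of 25 rose and 0 fell (adjusted p = 0.077), among them the collagenase MMP1 (log2 4.26 ± 0.51, 2 clones per group with 4 cultures each), from 0.314 to 5.85 CPM. Cholesterol synthesis genes fell in 2 of 28 in the knockdown clone (adjusted p = 0.00038, and adjusted p = 0.89 with an estimated correlation), with HMGCS1 from 152 to 47.0 CPM (log2 -1.69 ± 0.17). S phase genes passed there with MCM4 alone of 32 called, from 879 to 415 CPM (adjusted p = 2.8e-10, and adjusted p = 0.59 with an estimated correlation). The same counts passed when adjusted over the list alone. Genes of chromosome segments that changed as a block were not left out of these lists.

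Segments of 20 Mb with a median at least 0.3 from 0 (log2) numbered 158 over the 10 lines of 149 segments each, each set against the median of the 10 lines. The segment at the start of chromosome 20, which holds JAG1, was lower in MYO10 knockout clones 98 (-0.64) and 99 (-0.42) as in JAG1 knockout clone 35 (-0.56). The first segment of chromosome 5 was lower in clones 98 (-0.53), 99 (-1.25) and 84 (-1.03), and higher in clone 72 (0.44). The next was lower in clones 99 (-0.79) and 84 (-0.70), and the one after it in clone 84 (-0.64). In followers, the last segment of chromosome X (median 1.38) and a segment of chromosome 19 (1.15, and -0.51 in leaders) were higher.

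Of 11365 genes at 5 CPM or more in a line, 116 had no count in any culture of another line. X-linked genes may be over-represented among them, as a hypothesis: 11 of 380 X-linked genes were of this kind, 9.48% of the 116 against 3.34% of the background (odds ratio 3.09, 1.48 to 5.82, Fisher's exact p = 0.0017). Genes are not independent replicates in this test, which the p-value takes them to be.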
